A study of Homo sapiens with 4 samples.

How the data were processed

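Gene expression was measured in 4 samples of CL1-5, a human lung cancer cell line, with 1 Affymetrix array for each of 4 stable lines: an empty pcDNA3.1 vector control, a line carrying a KEAP1 expression construct, a luciferase shRNA control and a line carrying an shRNA against NRF2. Per the labels' protocols, cells were selected with G418 or puromycin, total RNA was extracted with a column kit, and biotinylated cRNA was prepared by the manufacturer's protocol. The tool named in the submitters' processing notes is MAS5, with no version. The normalization and the centring are not given in the sources used here.

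The deposited values are on a log scale taken here as log2, and they hold no signal level. In all 54675 probe sets the 2 values of the vector and KEAP1 pair sum to 0 within 1e-06 on the deposited scale, and so do the 2 values of the luciferase shRNA and NRF2 shRNA pair. Each pair had therefore been centred on its own middle before deposit, and the difference of its 2 columns is the log2 ratio of treated over control. The deposited column medians were -0.0046 for the vector control, 0.0046 for KEAP1 overexpression and 0 for both shRNA lines. The log base is inferred. The deposited values step like 32-bit floats of raw log values between 2 and 16, except in 8 probe sets with finer steps, which would need a raw value under 2. In 1077 probe sets the 2 values of a pair miss each other by the step of a raw value between 8 and 16, which is beyond the range of a log10 scanner signal. A natural log is not excluded by this, and under it every fold change given here would be larger. The direction follows from the columns, which are named by sample.

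The same rounding steps give a coarse level class. A probe set whose values carry the finest step had a raw log value under 4 on at least 1 array of either pair (14484 probe sets, the lowest class). Others were placed under 8 (21895, the middle class), and those whose values all fit the coarsest step (18296) form the highest class. On simulated values all probe sets assigned to the lowest class were truly under 4, and 75.0% of those under 4 were found in the simulated KEAP1 pair. The rest fell into a higher class, so the middle and highest classes can also hold dim probe sets. The deposited value of the treated array was exactly 0 in 1820 probe sets of the KEAP1 pair and in 2187 of the NRF2 pair. A value of 0 fits every step, so it says nothing about the level. Detection calls and background are unknown here, so a ratio of a dim probe set cannot be told from one of a bright probe set beyond this class.

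A gene's log2 ratio was the mean over its probe sets, using the 41097 probe sets with 1 gene in the platform annotation. The 1801 probe sets with several genes and the 11777 with none were left out of gene-level results. Of the probe sets with 1 gene, 41043 matched a current RefSeq gene (GRCh38.p14 table, used for names only) by its Entrez identifier, and 0 symbols needed an update. This gave 19775 genes, of which 9252 had 1 probe set. The plan made before the data were examined had used the probe set with the highest signal and a floor on low signals. Neither is possible without levels, so the mean over probe sets, also named in that plan, was used. With no replicate arrays there is no test, no p-value and no replicate error, and the difference between 2 arrays compares those arrays and not the conditions. The number of arrays limits the precision of every value.

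In place of replicate error, the spread of a ratio was taken as the pooled SD of log2 ratios among probe sets of one gene, over the 10523 genes with more than 1 probe set. It was 0.24 in the KEAP1 pair and 0.18 in the NRF2 pair, and it covers differences between probe sets on the same arrays only. A value given as ± SD below is the SD over a gene's own probe sets, with their number as n. A gene was counted as higher or lower at a 2-fold difference, a log2 ratio of 1 or more either way. A gene list's median was placed among the medians of 10000 random lists of the same size, matched on the number of probe sets and the level class. The plan had matched on mean signal, which needs levels. The matching used was chosen in its place once the values were seen to hold none. This percentile describes these arrays and is not a test. The calling step was tested on simulated data over 19775 genes. In the simulated KEAP1 pair it called 48 of 50 genes changed 3-fold, 49 of 50 changed 6-fold, 0 of 50 changed 1.5-fold and 0 of 19575 unchanged genes. In the simulated NRF2 pair it called 48 of 50 genes changed 3-fold, 50 of 50 changed 6-fold, 0 of 50 changed 1.5-fold and 0 of 19575 unchanged genes. The simulated noise was independent between probe sets, with the spread among probe sets of one gene in each level class. It held no noise shared by a gene's probe sets and no difference between arrays or lines. These counts are therefore a check of the calculation and not a rate of false calls for these arrays.

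The 25 gene lists (412 genes, 371 of them measured here) and the rule for named genes were fixed before the data were examined. The rule names the targeted gene, S100P, the 10 highest and 10 lowest genes whose probe sets all have the same sign, up to 4 members of each list with the largest ratios, and the 10 genes that are lowest or highest in both comparisons. Alternatives changed the scaling, the probe sets that represent a gene and the fold threshold. The planned floors, quantile normalization, highest-signal probe set, exchange of the 2 controls and comparison of the 2 controls with each other need signal levels and were not run. Some genes of the lists have no probe set naming them alone and were not analysed here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.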

Results

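Transcript levels were profiled in CL1-5, a human lung cancer cell line, in lines labelled as carrying a KEAP1 construct or an shRNA against NRF2, and in their controls. KEAP1 is the adaptor of a ubiquitin ligase that marks the transcription factor NRF2 (gene symbol NFE2L2) for degradation, and NRF2 drives antioxidant and detoxification genes. The 4 groups hold 1 array each: KEAP1 overexpression and its vector control, and NRF2 shRNA and its luciferase shRNA control. The deposited values keep the ratio within each of these 2 pairs and no signal level, so the controls could not be set against each other. No difference has a replicate check, and the number of arrays limits the precision. Log2 ratios are treated over control, with a log base inferred from the values.

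The targeted transcripts were examined first, and neither differed beyond the spread. The single KEAP1 probe set had a log2 ratio of 0.03 in the KEAP1 overexpression pair, well within the spread of 0.24 for that pair. Whether this probe set reads the transcript of the construct is not known here, so it does not check the label. NFE2L2 had a log2 ratio of 0.04 ± 0.13 (SD, n = 3 probe sets) in the NRF2 shRNA pair. Its probe set in the highest level class was at -0.11, and the others were at 0.13 and 0.10, all within the spread of 0.18 for that pair. NFE2L2 was therefore not measurably lower on the array labelled NRF2 shRNA, and the directions below are those of the arrays labelled KEAP1 overexpression and NRF2 shRNA.

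The comparison of KEAP1 overexpression with the vector control asks which transcripts differ in the line labelled as overexpressing the NRF2 repressor. The chemokine genes CCL5, CXCL11 and CXCL10 were the highest on the array labelled KEAP1 overexpression, and the collagenase gene MMP1 and the protease inhibitor gene CSTA the lowest. CCL5, a chemokine that attracts T cells, was 6.93-fold higher with a log2 ratio of 2.79 ± 0.04 (SD, n = 3 probe sets). MMP1 was 6.06-fold lower with a log2 ratio of -2.60 in 1 probe set. Of 19775 genes, 43 were at least 2-fold lower and 21 at least 2-fold higher in their mean over probe sets. Of single probe sets naming 1 gene, 122 were at least 2-fold lower and 48 higher. At a 1.5-fold threshold the gene counts were 218 lower and 195 higher.

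The interferon-induced chemokines CXCL11, at 2.29 ± 0.25 (SD, n = 2 probe sets), and CXCL10, at 2.28, followed CCL5 among the 10 highest genes. The antiviral gene RSAD2 had a log2 ratio of 1.96 ± 0.16 (SD, n = 2 probe sets), and OASL, of the oligoadenylate synthetase family, one of 1.37 ± 0.0012 (SD, n = 2 probe sets). PLAAT4, IL4I1 and the type III interferon gene IFNL2 were at 1.76, 1.48 and 1.42. IFNL2 was in the lowest level class and has a near-identical copy, IFNL3, so its share of the signal is uncertain. The inflammatory cytokine gene TNF was at 1.31 and TH, which encodes tyrosine hydroxylase, at 1.60.

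Among the 10 lowest genes, the protease inhibitor genes CSTA and SPINK2 had log2 ratios of -2.48 and -2.01, and MMP10, stromelysin-2, one of -1.98. CSTA and MMP10 were in the lowest level class, so on at least 1 array each was near the bottom of the scale. SUN3 was at -1.78. The calcium-binding protein gene S100P was 3.31-fold lower, at -1.73, and DKK1, a secreted Wnt inhibitor, was at -1.69. DNER, GARIN5A and the collagen VI chain gene COL6A3 were at -1.68, -1.59 and -1.58. Each of these 10 genes rested on 1 probe set.

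**Figure D1:**
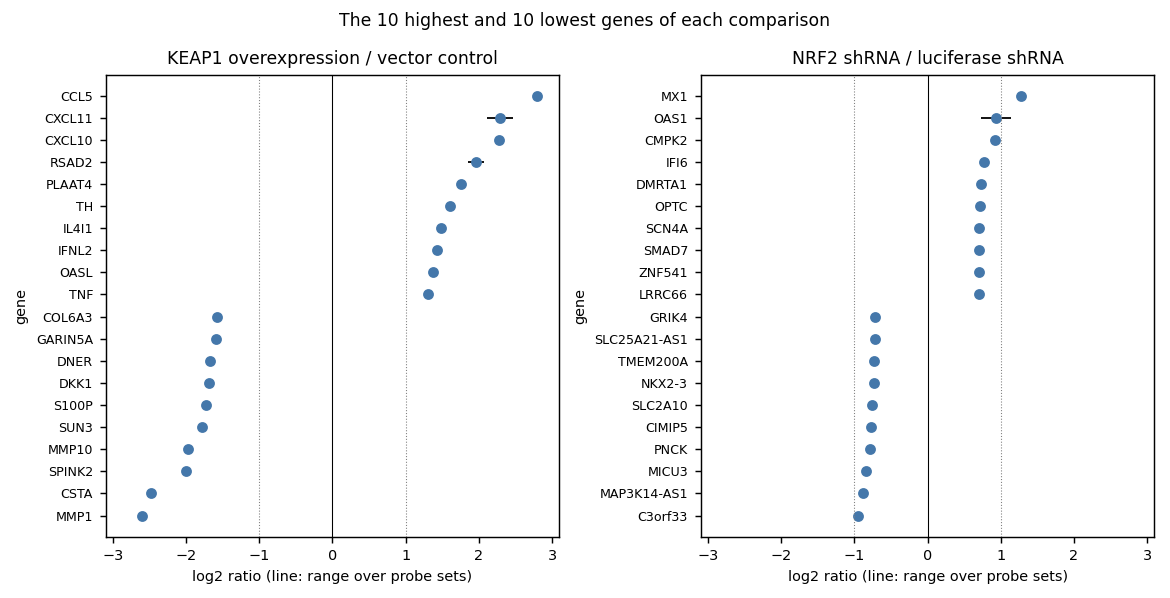
Log2 ratios (horizontal axis) of the 10 highest and 10 lowest genes (vertical axis) in KEAP1 overexpression over vector control and in NRF2 shRNA over luciferase shRNA, with 1 array per group. Points are means over a gene's probe sets, black lines span its probe sets where it has more than 1, and dotted lines mark 2-fold; every gene shown for the KEAP1 pair lies beyond them, from MMP1 at -2.60 to CCL5 at 2.79, and MX1 alone does in the NRF2 pair at 1.28.

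The NRF2 target lists did not stand apart from random lists in the KEAP1 pair. Of 15 antioxidant and glutathione genes, 0 were 1.5-fold lower or higher, with a list median of 0.04 at percentile 73.3 of random lists. The cystine transporter gene SLC7A11 was at -0.37 ± 0.33 (SD, n = 3 probe sets), GPX2, of the lowest level class, at 0.34 ± 0.70 (SD, n = 2 probe sets) and the quinone reductase gene NQO1 at 0.33 ± 0.20 (SD, n = 3 probe sets). Of 22 detoxification and export genes, 1 was 1.5-fold higher and 0 lower, with a median of -0.00033 at percentile 31.2 and a mean of 0.03. That gene was PIR, at 0.92; GSTM3 was at -0.34 ± 0.23 (SD, n = 2 probe sets) and GSTP1 at 0.33. NADPH and pentose phosphate genes had a median of 0.06 at percentile 86.5, with malic enzyme ME1 at 0.31 ± 0.04 (SD, n = 3 probe sets). The KEAP1-NRF2 regulators had a median of 0.05 at percentile 82.4, with NFE2L3 at 0.32 ± 0.02 (SD, n = 2 probe sets).

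The matrix protease list and the integrin and laminin list had medians below most random lists in the KEAP1 pair. Of 18 matrix proteases and their inhibitors, 2 were at least 2-fold lower (MMP1 and MMP10), 5 at least 1.5-fold lower and 0 at least 1.5-fold higher. Their median of -0.29 was below all 10000 random lists; it was -0.21 without probe sets of the lowest level class. MMP3, stromelysin-1, of that class, was at -0.92, and PLAT, tissue plasminogen activator, at -0.81. Protease inhibitor genes were lower too, TIMP1 at -0.59 and TIMP2 at -0.53 ± 0.17 (SD, n = 3 probe sets). MMP9, at 0.46, and PLAUR, at 0.38 ± 0.06 (SD, n = 3 probe sets), were among the 4 genes above 0. The list median therefore does not describe proteases alone. Of 15 integrins and laminins, 12 were below 0 and 3 at least 1.5-fold lower, with a median of -0.19 at percentile 0.040. Using for each gene the probe sets of its highest level class moved this median to -0.32. LAMB1 was at -0.65 ± 0.05 (SD, n = 2 probe sets), ITGA3 at -0.63 and ITGB3 at -0.62 ± 0.42 (SD, n = 7 probe sets), which was -0.95 in its highest level class.

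The medians of the epithelial and mesenchymal lists did not stand apart from random lists, although single members were at least 2-fold lower. EPCAM, an epithelial adhesion molecule in the lowest level class, was at -1.21, and the splicing regulator ESRP1 at -0.61 ± 0.66 (SD, n = 2 probe sets), which was -1.07 in its highest level class. The epithelial list had a median of 0.04 at percentile 60.2 and a mean of -0.07; the median was 0.13 with only probe sets lacking _s_ or _x_ in their ID. Among 16 mesenchymal genes, COL6A3 and the collagen cross-linking enzyme LOX, at -1.12 ± 0.43 (SD, n = 3 probe sets), were at least 2-fold lower. TGFBI was at -0.70 and fibronectin, FN1, at -0.51 ± 0.35 (SD, n = 7 probe sets). FN1 was -0.07 with only probe sets lacking _s_ or _x_ in their ID and -0.79 in its highest level class. The list median was -0.06 at percentile 13.2, and -0.0067 with only probe sets lacking _s_ or _x_. The mean of this list was lower, at -0.26, with 3 genes at least 1.5-fold lower and 0 at least 1.5-fold higher. Of its genes 10 were below 0 and 6 above. Actin and motility regulators had a median of 0.04 at percentile 83.0 and a mean of -0.03, and the median was -0.04 with the highest level class of each gene and -0.03 without the lowest, with CCN2 at -0.71 and CDC42 at 0.34 ± 0.17 (SD, n = 5 probe sets).

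S100P was the only one of 19 S100 genes at least 2-fold different in the KEAP1 pair. S100A3 and S100A4 had ratios of the opposite sign, 0.92 and 0.69. The list median was 0.13 at percentile 94.1, with 3 genes below 0 and 15 above.

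All 19 measured interferon-stimulated genes had ratios above 0 in the KEAP1 pair, and their median of 0.33 was above all 10000 random lists. Of these genes 0 reached 2-fold and 4 reached 1.5-fold. IFIT2 was at 0.97 ± 0.18 (SD, n = 2 probe sets), the RNA sensor gene IFIH1 at 0.76 ± 0.35 (SD, n = 3 probe sets) and OAS1 at 0.62 ± 0.26 (SD, n = 2 probe sets). The 17 NF-kB and inflammatory cytokine genes went both ways, with a median of 0.07 at percentile 78.7. CCL5 and IL6, at 0.79, were higher, and IL1B, at -1.18 ± 0.17 (SD, n = 2 probe sets), and CXCL3, at -0.78, were lower.

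Hypoxia and glycolysis genes had a low list median in the KEAP1 pair, with 12 of 16 below 0 and a median of -0.16 at percentile 0.46. EGLN3, an oxygen-sensing hydroxylase, was at -0.63 ± 0.05 (SD, n = 2 probe sets) and VEGFA at -0.39 ± 0.13 (SD, n = 4 probe sets). The immediate early gene EGR1 was at -1.03 ± 0.29 (SD, n = 3 probe sets) and DUSP6 at -0.59 ± 0.11 (SD, n = 3 probe sets), in a list with a median of -0.07 at percentile 10.1, and of 0.04 with only probe sets lacking _s_ or _x_. Cell cycle genes had a median of -0.01 at percentile 40.6, with CCNE2 at -0.55 ± 0.08 (SD, n = 2 probe sets) and TOP2A at -0.49 ± 0.14 (SD, n = 3 probe sets). The p53 targets had a median of 0.06 at percentile 77.1, with ZMAT3 at -0.58 ± 0.30 (SD, n = 5 probe sets). The unfolded protein response and ATF4 list had a median of -0.08 at percentile 6.25, with the chaperone gene HSPA5 at -0.43 ± 0.0045 (SD, n = 2 probe sets). Heat shock, cholesterol synthesis, ribosomal and housekeeping lists had medians of -0.03, 0.01, -0.02 and 0.0094, at percentiles 35.4, 61.9, 34.6 and 66.4; the mean of the housekeeping list was -0.03. With only probe sets lacking _s_ or _x_, the cholesterol and housekeeping medians were -0.08 and -0.07.

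Endothelial markers had a median of -0.18 at percentile 0.63 in the KEAP1 pair, with KDR at -1.33 and ESAM at -0.60. TIE1 was at -1.08 ± 1.79 (SD, n = 2 probe sets), and its probe sets disagreed: the one without _s_ or _x_ in its ID was at 0.19. With such probe sets alone the list median was -0.06. In its highest level class TIE1 was -2.34. Immune, fibroblast and lung lineage markers had medians of 0.10, 0.06 and 0.11, at percentiles 82.0, 70.0 and 87.4. The fibroblast median was 0.15 with the median over probe sets, and the immune median -0.00057 with only probe sets lacking _s_ or _x_. The basal keratin gene KRT14, of the lowest level class, was at 1.03. All 18 probe sets of the hybridization spike-ins were lower on the array labelled KEAP1 overexpression, with a median of -0.12. The ratio of the 3' probe set minus that of the 5' probe set, a sign of RNA integrity, was -0.12 for ACTB and -0.03 for GAPDH.

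**Figure D2:**
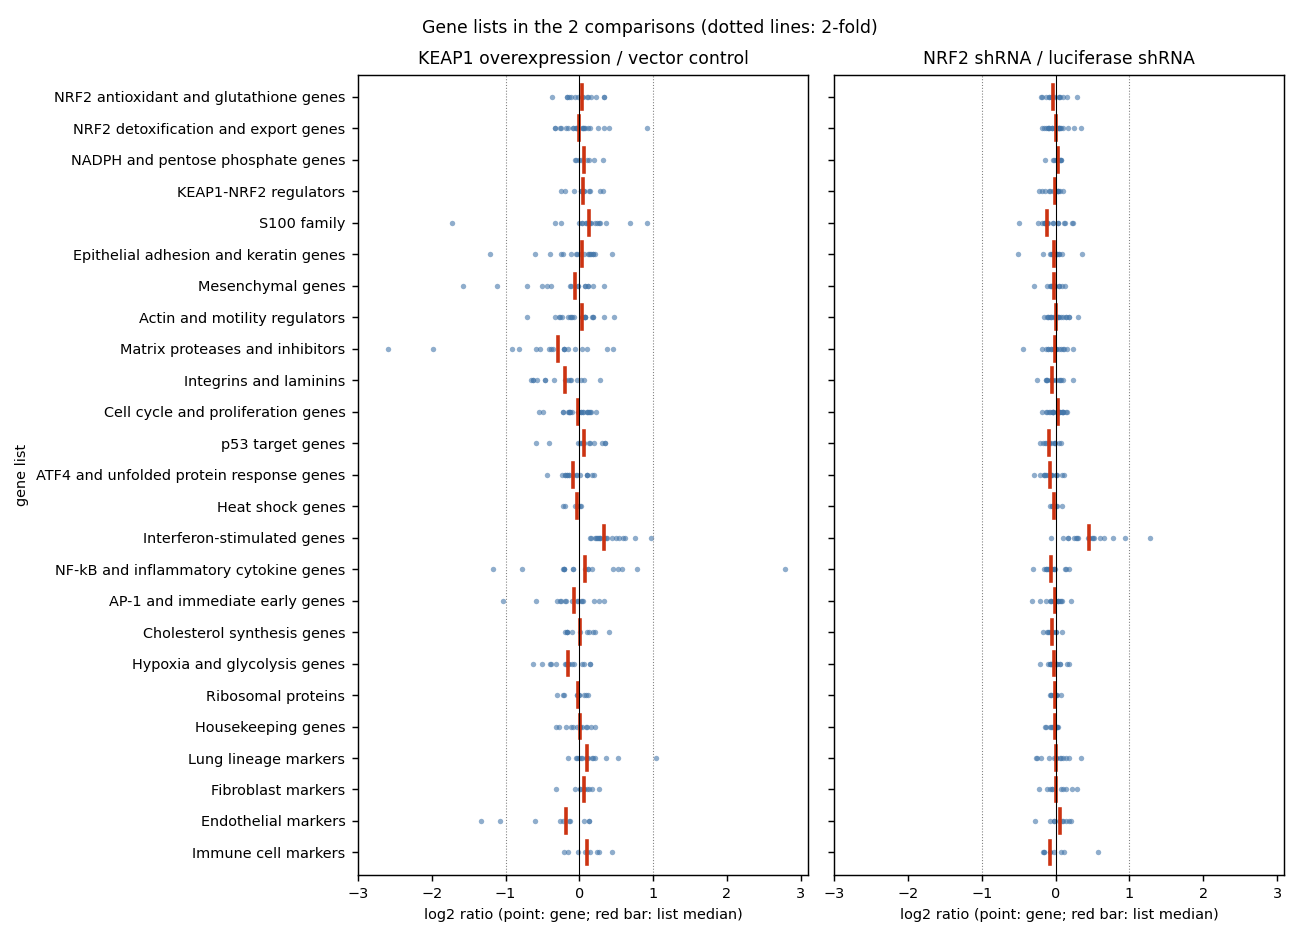
Log2 ratios (horizontal axis) of the measured members of the 25 gene lists (vertical axis) in both comparisons, with 1 array per group. Each point is a gene, the red bar is the list median and dotted lines mark 2-fold. The medians of the interferon-stimulated genes, 0.33 and 0.45, lie to the right of 0. The median of the matrix proteases and inhibitors in the KEAP1 pair, -0.29, lies to the left, with 4 of 18 genes above 0.

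The comparison of NRF2 shRNA with luciferase shRNA asks which transcripts differ in the line labelled as carrying an shRNA against NRF2. Differences were smaller than in the KEAP1 pair, and MX1, OAS1 and CMPK2 were the highest. MX1, an interferon-induced antiviral GTPase, was 2.43-fold higher with a log2 ratio of 1.28 in 1 probe set. It was the 1 gene of 19775 whose mean over probe sets was at least 2-fold higher, and 0 were at least 2-fold lower; of single probe sets naming 1 gene, 9 were at least 2-fold higher and 1 lower. At 1.5-fold, 33 genes were lower and 29 higher. Across genes the SD of the log2 ratio was 0.15, against 0.24 in the KEAP1 pair. The intraclass correlation among probe sets of one gene was 0.05, against 0.28 in the KEAP1 pair, so single probe sets say less about their gene here.

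Of 19 interferon-stimulated genes, 18 had ratios above 0 in the NRF2 pair and 5 reached 1.5-fold, and the list median of 0.45 was above all 10000 random lists. OAS1 was at 0.93 ± 0.29 (SD, n = 2 probe sets), IFI6 at 0.77 and OAS2 at 0.66 ± 0.10 (SD, n = 3 probe sets). CMPK2, an interferon-induced nucleotide kinase gene outside the list, was at 0.92. The rest of the 10 highest were DMRTA1, OPTC, SCN4A, ZNF541, LRRC66 and SMAD7, an inhibitor of TGF-beta signalling, between 0.70 and 0.73, with DMRTA1 and ZNF541 in the lowest level class. The lowest were C3orf33 at -0.95, MAP3K14-AS1 at -0.88, MICU3 at -0.84, PNCK at -0.79, CIMIP5 at -0.77 and the glucose transporter gene SLC2A10 at -0.76. NKX2-3, TMEM200A, SLC25A21-AS1 and GRIK4 followed, between -0.73 and -0.71, with SLC2A10 and GRIK4 in the lowest level class. The higher classes can also hold dim genes. NKX2-3, at -0.728479, and DMRTA1, at 0.728479, had ratios of the same size, and the cause of this repeat was not tested. Each of these 10 lowest genes rested on 1 probe set.

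The NRF2 target lists did not stand apart from random lists in the NRF2 pair either. The antioxidant and glutathione genes had a median of -0.03 at percentile 24.7, with 9 of 15 below 0. Heme oxygenase 1, HMOX1, was at 0.29, NQO1 at -0.20 ± 0.10 (SD, n = 3 probe sets) and SLC7A11 at -0.18 ± 0.07 (SD, n = 3 probe sets). The detoxification and export genes had a median of 0.0043 at percentile 70.2, with the exporter gene ABCC2 at 0.25. UGT1A6, which shares exons with its UGT1A neighbours and is uncertain, was at 0.34. NADPH and pentose phosphate genes had a median of 0.03 at percentile 85.7, which changed sign with other choices of probe sets, and PGLS was at -0.15 ± 0.13 (SD, n = 4 probe sets). The KEAP1-NRF2 regulators had a median of -0.0028 at percentile 59.8 and a mean of -0.04, with SQSTM1 at -0.22 ± 0.17 (SD, n = 5 probe sets).

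S100P was 1.41-fold lower on the array labelled NRF2 shRNA, at a log2 ratio of -0.50. The S100 list had a median of -0.11 at percentile 0.39, with 13 of 19 genes below 0 and S100A4 at -0.24. The p53 targets had a median of -0.09 at percentile 1.92, with 11 of 13 below 0 and TP53I3 at -0.21. The ATF4 and unfolded protein response list had a median of -0.07 at percentile 2.92, and -0.0022 with only probe sets lacking _s_ or _x_, with DDIT4 at -0.30 and HSPA5 at -0.22 ± 0.04 (SD, n = 2 probe sets). The polyA spike-ins, which are added to the RNA before labelling, had a median of -0.18 over 24 probe sets, and the lowest was at -0.87. Of these, 20 were below 0 and 3 above. In the KEAP1 pair the same probe sets had a median of -0.09, with 19 below 0 and 4 above.

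The lists of matrix proteases and inhibitors, integrins and laminins, and hypoxia genes had low medians in the KEAP1 pair. In the NRF2 pair their medians were -0.01, -0.05 and -0.02, at percentiles 45.8, 9.22 and 34.5. MMP1 was at 0.23, MMP10 at -0.45 and LAMA5 at -0.26. Epithelial, mesenchymal and actin lists had medians of -0.02, -0.02 and 0.0065, at percentiles 37.4, 37.9 and 76.2. The epithelial keratin gene KRT19 was at -0.51 ± 0.07 (SD, n = 2 probe sets), CDH3 at 0.36, TWIST1 at -0.30 and CCN2 at 0.31. Cell cycle, heat shock, NF-kB and AP-1 lists had medians of 0.03, -0.02, -0.06 and -0.01, at percentiles 95.04, 40.6, 10.1 and 47.2. Cholesterol, ribosomal and housekeeping lists had medians of -0.05, -0.01 and -0.0076, at percentiles 15.3, 49.9 and 53.5. Lung lineage, fibroblast, endothelial and immune markers had medians of 0.0078, 0.0094, 0.07 and -0.07, at percentiles 69.6, 71.0, 95.3 and 11.2; the immune list had a mean of 0.01, with CD3E at 0.57. With only probe sets lacking _s_ or _x_, the matrix protease, hypoxia and AP-1 medians were 0.05, 0.06 and 0.03, and the actin, fibroblast and endothelial medians -0.02, -0.04 and -0.01. The lung lineage and cholesterol medians were then 0.06 and -0.09, and the cell cycle median was 0.0020 with the highest level class of each gene.

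Of the 50 list medians in both comparisons, 8 lay outside the central 95% of random lists, where 2.5 would be for random draws. They were the interferon-stimulated genes in both pairs, and the matrix protease, integrin and laminin, hypoxia and endothelial lists in the KEAP1 pair. The S100 and p53 target lists in the NRF2 pair were the rest. The random lists draw genes without regard to function, while genes of a fixed list may vary together between any arrays. The value of 2.5 is therefore not a chance rate for the fixed lists, and no excess over chance is concluded.

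KEAP1 overexpression and NRF2 shRNA are both meant to lower NRF2 activity, so their ratios were compared gene by gene. The pairs share no array. Across 19775 genes, which are not independent replicates, Pearson's r was -0.02 and Spearman's rho was -0.02. At 2-fold, 0 genes were lower in both and 0 higher in both. At 1.5-fold, IGDCC4 and CFAP54 were lower in both, 2 genes where independent lists would share 0.364. CMPK2, OAS1 and IFIT3 were higher in both, 3 genes against 0.286. ND6 and SUN3 were lower with KEAP1 and higher with NRF2 shRNA, 2 genes against 0.320, and AFP went the other way, 1 gene against 0.325; ND6 and AFP were named after their values were seen. At a log2 ratio of 0.32 or more either way, a threshold chosen after the data were seen, 69 genes were higher in both against 38.8 for independent lists, and 87 were higher with KEAP1 and lower with NRF2 shRNA against 37.7. At that threshold 39 were lower in both against 29.8, and 38 were lower with KEAP1 and higher with NRF2 shRNA against 30.7. The values for independent lists take every gene as equally likely to pass. The spread among probe sets was larger in the lowest level class than in the highest, 0.25 against 0.20 in the KEAP1 pair and 0.22 against 0.13 in the NRF2 pair. At both of these thresholds the counts exceeded those values in every direction, opposite ones included, so no excess over chance is concluded.

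S100P and MMP10 were among the 10 genes that ranked lowest in both pairs, S100P at -1.73 and -0.50 and MMP10 at -1.98 and -0.45. IGDCC4 was at -0.70 and -0.71, and LRP4, of the LDL receptor family, at -0.52 and -0.61. CFAP54, TMEM170B, PPM1F-AS1, LOC100287387, RBM24 and a probe set annotated to MIR34A made up the rest. MMP10, CFAP54, TMEM170B and PPM1F-AS1 were in the lowest level class. The 10 that ranked highest in both included the interferon-induced genes CMPK2 at 0.65 and 0.92, OAS1 at 0.62 and 0.93, and IFIT3 at 0.59 and 0.60. RSAD2 was at 1.96 and 0.52 ± 0.51 (SD, n = 2 probe sets), TRIM22 at 0.51 and 0.56, and PARP9 at 0.45 and 0.58. ACTG1P25, INHA, AQP5 and RPL27A made up the rest, and ACTG1P25, INHA and TRIM22 were in the lowest level class.

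**Figure D3:**
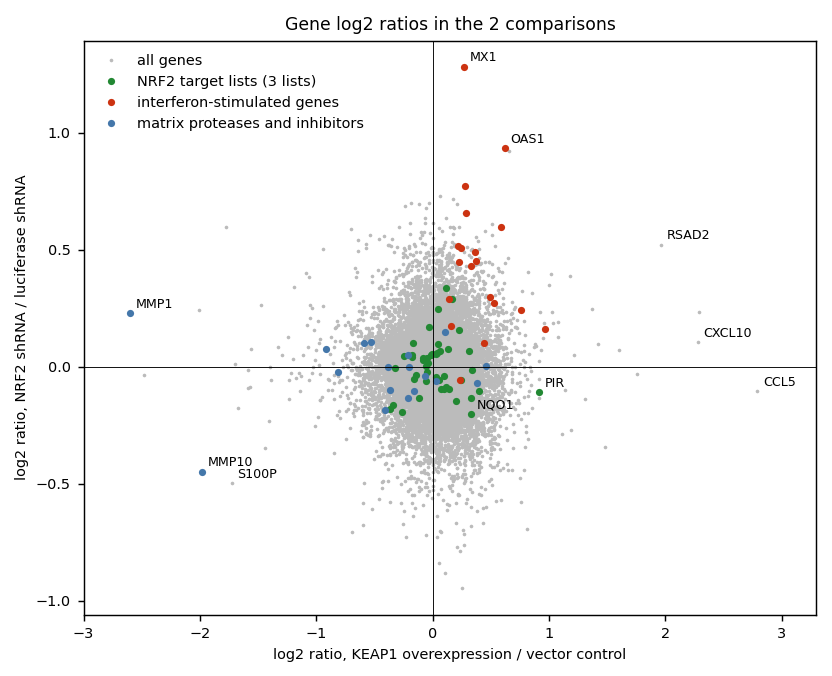
Gene log2 ratios in KEAP1 overexpression over vector control (horizontal axis) and in NRF2 shRNA over luciferase shRNA (vertical axis), with 1 array per group; each point is a gene, with 3 sets of lists coloured. Interferon-stimulated genes lie in the upper right, except 1 of 19 that is below 0 in the NRF2 pair, with medians of 0.33 and 0.45, and across all genes Pearson's r was -0.02.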

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

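All probe sets given here were singled out after their values were seen, and no explanation was tested for them. Probe sets that name no gene or several genes took no part in the comparisons between genes, and 3 of these 13578 were at least 3-fold higher on the array labelled KEAP1 overexpression than on its vector control, and 0 at least 3-fold lower. At 2-fold more of them were lower, 29, than higher, 12. In the NRF2 shRNA pair 3 were at least 2-fold higher and 0 lower. Of the 3 at least 3-fold higher, the first, unnamed here, had a log2 ratio of 2.90. Another, shared by the type III interferon genes IFNL3 and IFNL2, had a log2 ratio of 1.88. The last, shared by the chemokine genes CCL3L3, CCL3L1 and CCL3, had a log2 ratio of 1.68.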

How the results depend on the processing

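No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The planned floors, quantile normalization, highest-signal probe set and exchanged or compared controls were not run, since the deposited values hold no levels. The median over probe sets, the level-class settings, the matching of random lists and the threshold of a log2 ratio of 0.32 were chosen after seeing the data. Under 6 changes of scaling or probe sets the KEAP1 counts of 43 and 21 genes stayed within 1.5 times, as did 0 genes lower with NRF2 shRNA; the count of 1 gene higher became 2 with only probe sets lacking _s_ or _x_ in their ID. Thresholds moved most counts: at 1.5-fold and 3-fold the KEAP1 pair had 218 and 9 genes lower and 195 and 6 higher, and the NRF2 pair 33 lower at 1.5-fold and 29 and 0 higher at 1.5-fold and 3-fold. Genes lower in both numbered 2 at 1.5-fold and 39 at a log2 ratio of 0.32, and genes higher in both 3 and 69, against 0 at 2-fold. The median of the NADPH list in the NRF2 pair, 0.03, became -0.014 with the median over probe sets, -0.033 with the highest level class of each gene and -0.022 without the lowest class; the cause was not tested. Of 1496 alternative values of named genes, 1456 stayed within 1 spread of the value reported. Of the others 14 also changed sign, in 9 results. Of genes at least 2-fold different this was TIE1 alone, in the KEAP1 pair, which became 0.19 with only probe sets lacking _s_ or _x_, because this leaves 1 of its 2 discordant probe sets. COL1A1 in the KEAP1 pair, at -0.32, became 0.34 with its highest level class and 0.28 without the lowest class. The rest, in the NRF2 pair, were CXCL2, ERG, HERPUD1, HSPH1, ME1, RHOC and TXN; the cause was not tested. Of 300 alternative list medians 270 stayed within 1 SD of random lists, and of the others 16 changed sign, for 12 list medians. Signal over background is unknown, which limits what can be said of dim genes.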

Other observations

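The gene families and all tests here were chosen after the results were seen, except the test of measurement noise. The median of the NRF2 targets, whose members go both ways, was taken not to decide for single targets. That choice was made after their value was seen. Families sharing a symbol stem were ranked against 1000 random lists each, over 458 families of 6 to 60 genes. In the KEAP1 pair the pregnancy-specific glycoproteins (PSG) had a median log2 ratio of -0.48, with 8 of 9 genes below 0; these genes are near-identical, so their separate values are uncertain. The guanylate-binding proteins (GBP), interferon-induced GTPases, had a median of 0.45, with 6 of 7 genes above 0, and the apolipoprotein L family (APOL) 0.47, with 4 of 6 above 0. Mitochondrial large-subunit ribosomal proteins (MRPL) had a median of 0.12, with 39 of 49 genes above 0. The stems MAN, mostly mannosidases, and TM, which joins several families of membrane proteins, had medians of -0.27, with 7 of 9 genes below 0, and -0.25, with 10 of 15 below 0. In the NRF2 pair the interferon-induced IFI genes had a median of 0.32, with 7 of 8 above 0, and the CXCL chemokines 0.15, with 10 of 14 above 0. The stems KIR, APOL and SIGLEC ranked next, with medians of 0.16, 0.16 and 0.14. Of their genes 9 of 13, 5 of 6 and 8 of 11 were above 0. High ranks were thus not particular to IFI and CXCL genes. A single probe set of MAP2K5, of the lowest level class, was at 3.56 in the KEAP1 pair, and the other probe sets of the gene were between -0.35 and 0.05. In the NRF2 pair the highest single probe set naming 1 gene, of SCD5, was at 1.74, above MX1, while the mean over the 4 probe sets of SCD5 was 0.28 and the lowest was at -0.35.

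The median of the interferon-stimulated genes was above all 10000 random lists in both pairs, with 19 of 19 genes above 0 in the KEAP1 pair and 18 of 19 in the NRF2 pair. The list median stood at least 5.53 SD of random lists above the median of all genes in each pair. This restates its place above all random lists, so it is no separate test of a scaling shift. A shift equal for all genes would move the list and the random lists alike. Known NRF2 targets as a set were not lower in either pair. Their pooled median lay 0.661 SD above random lists in the KEAP1 pair and 0.221 SD above in the NRF2 pair. Of 45 targets, 0 were 1.5-fold lower in either pair, and 1 was 1.5-fold higher, in the KEAP1 pair. Members went both ways, with 21 below 0 in the KEAP1 pair and 23 in the NRF2 pair, so lower expression of some of them stays open. For a handling difference shared by all genes, the Pearson correlation between the pairs across genes outside the list was -0.0214. Across all genes its bootstrap SD over genes was 0.0087. If all differences shared by probe sets were common to both pairs, the correlation would reach about 0.154, so the value argues against that. A handling difference that makes up a smaller part of the differences stays open. A response to the introduced DNA and RNA, or differences between stable lines, may also explain the pattern, and neither was tested.

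Differences were larger in the KEAP1 pair than in the NRF2 pair. Larger noise that is independent between probe sets of one gene is argued against as the whole cause. The covariance of ratios between probe sets of one gene was higher in the KEAP1 pair by 17.3 bootstrap SE. The spread among probe sets was also larger there. Noise that moves the probe sets of a gene together would raise this covariance too. It cannot be told apart here from a larger difference between the KEAP1 line and its control. Whether such a difference would come from KEAP1 or from separate selection of the lines was not tested.

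The KEAP1 transcript was not higher in the KEAP1 pair, with a log2 ratio of 0.032. A probe set outside the construct could give this value whatever the construct does, and so could a construct that was not expressed. These cannot be told apart, because the probe positions and the sequence of the insert are not used here.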
